A study of Mus musculus with 2 samples.

How the data were processed

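Total RNA was sequenced from the left cerebral cortex of 2 female mice aged 25 days, offspring of a cross of the C57BL/6 and CAST strains (strain label B6CASTF1/J). Each library was made from 300 ng of RNA with ERCC spike-ins, which are synthetic RNAs added to the sample, per the labels. The labels number the libraries as biological replicates 1 and 2 and give each tissue its own animal number, but cite the same donor identifier for both. They were treated as separate animals on the animal numbers, and if that is wrong the spread between them covers preparation only. The samples form 1 group, so no contrast between conditions exists and every comparison is either within a library or between the 2 animals.

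Per the accompanying description of the files, the authors quantified each library in a pair of ways on assembly mm10 with GENCODE annotation M21. The alignment-based tables were made from reads aligned to the transcriptome, and the FASTQ-based transcript table was made directly from the reads. The names and versions of the aligner and quantifiers are not given in the sources used here. The deposited alignment-based tables give an expected count per gene, which is an estimate that need not be whole because reads matching several places are divided between them. They also give TPM and FPKM per gene, per the file headers, with TPM scaled by the authors over all entries, spike-ins included. The percent of a gene's TPM in each transcript was taken from the deposited alignment-based transcript table. The deposited FASTQ-based table gives an estimated count and TPM per transcript, which were summed per gene here.

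Each gene table holds 81881 entries, of which 55536 are annotated genes, 96 are spike-ins, 1 is the phiX174 control and 26248 carry only a number. All 55536 annotated identifiers matched GENCODE M21, from which symbols, classes and mm10 coordinates were taken. The numbered entries name no gene, stayed out of library sizes and tests, and took 6.39e-06% of the expected counts in replicate 1 and 1.81e-05% in replicate 2. For 86 annotated genes the FASTQ-based table has no entry.

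Expected counts summed to 31301126 in replicate 1 and 27182336 in replicate 2, and FASTQ-based estimated counts to 31509602 and 28037421. A count of 0 allows up to 3 counts, which is 0.0962 CPM (counts scaled to the size of the library) in replicate 1 and 0.111 CPM in replicate 2. Intervals and floors cover counting error only, because the reads carry no molecular identifiers.

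Genes were called detected at a TPM of at least 1 in both libraries. Levels of a gene list are the median over members of log2(TPM + 1) averaged over the 2 libraries, set against the detected nuclear protein-coding genes. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), which gave TMM factors of 0.987 and 1.01 and a common biological coefficient of variation over genes with at least 1 CPM. DESeq2 1.42.0 size factors served as an alternative scaling only. CPM between the animals were compared as log2(CPM + 1), a scale that understates differences of low genes. For each list the median log2 ratio of replicate 2 over replicate 1 was set against 10000 random lists of the same size, drawn from 200 genes nearest in mean expression to each member. Lists outside the central 95% of those medians are described as outside the random range. Genes of a list are regulated together, so random lists understate the spread a list can have by chance. Single genes were compared by a rule of size, a 2-fold difference at a mean CPM of at least 5, because 1 library per animal gives no p-value. Intervals of count ratios are exact 95% intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

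The 33 gene lists, 14 gene pairs and 20 isoform genes were fixed before the data were examined. The lists cover cell types (excitatory and inhibitory neurons, astrocytes, oligodendrocyte precursors, myelinating oligodendrocytes, microglia, endothelial, mural, meningeal, choroid plexus and ependymal, and erythroid cells), upper and deep cortical layers, other brain regions (striatum, hippocampus, thalamus and hypothalamus, cerebellum), immediate early genes, heat shock and stress, interferon response, cell cycle, immature neurons, glutamate receptors, GABA-A receptors, sodium and potassium channels, perineuronal net and matrix, neuropeptides, imprinted genes, long non-coding RNAs, structured small RNAs, mitochondrial coding genes, replication-dependent histones and housekeeping genes. Genes are named by a rule fixed at the same time: the 10 most abundant nuclear protein-coding genes, the 2 to 4 most abundant members of each list, every pair, the isoform genes whose leading transcript differed between the quantifications plus Snap25, Mapt, Mbp and Gria2, up to 5 protein-coding genes higher and 5 lower in replicate 2 by the rule of size, and the 3 most abundant non-mitochondrial genes of any class. Other named genes are list members given to describe a list's spread or are stated to have been chosen after their values were seen.

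The steps were tested on simulated data, with counts for the 55536 genes drawn from the means and depths of these libraries for the comparison of replicate 2 with replicate 1. Of genes made to differ 3-fold, 100% passed the rule of size, against 2% of those made to differ 1.5-fold and 0 of 11537 unchanged genes. A simulated coefficient of variation of 0.1 was recovered as 0.0994 when no gene differed and as 0.124 with changed genes included. Of 100 unchanged lists of 12 genes, 3 fell outside the random range, and 8 of 8 lists made to differ 1.5-fold fell above it. Simulated genes varied independently with the same coefficient of variation, and these lists held only genes with at least 5 CPM. The rates therefore need not hold for the measured lists, whose genes vary together and in some lists have few reads. Alternatives covered pseudocounts, minimum levels, scalings (DESeq2, spike-ins, TPM as deposited), FPKM, the FASTQ-based quantification, and each library left out. A correction for GC content and length, an additional list of hypothalamic genes and a floor for members without reads were chosen after seeing the data. The bounds the authors gave for TPM were not used here. Some genes that the naming rule covers are not reported here, and the next most abundant members of their lists are given in places.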

Results

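Total RNA sequencing measured the transcriptome of the left cerebral cortex in 2 female C57BL/6 × CAST first-generation hybrid mice aged 25 days, replicates 1 and 2 of 1 group. The libraries held 31301126 and 27182336 expected counts. The question open to this design is what the juvenile cortex expresses and how far a pair of animals differ. Values below are means ± SD over the 2 animals (n = 2), in the deposited alignment-based TPM unless another unit is named, and coordinates are on mm10.

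The cortex expressed 12933 of 22015 annotated nuclear protein-coding genes (58.7%) at a TPM of at least 1 in both animals. By the same measure 805 of 10155 long non-coding RNA genes, 671 of 13525 pseudogenes, 213 of 6091 small structured RNA genes and 15 of 37 mitochondrial genes were detected, 15286 genes in all with the remaining classes. Across 28307 genes, which are not independent replicates, log2(TPM + 1) of the animals correlated with a Pearson r of 0.989 and a Spearman rho of 0.951. Over 17442 nuclear protein-coding genes these were 0.995 and 0.992. The common biological coefficient of variation by edgeR was 9.10% over 15683 genes. A chi-square of 7.84 per degree of freedom over 20441 genes showed that the libraries differed by more than sampling noise, so they were not a single library deposited under a pair of names. This does not tell separate animals from separate preparations of the same tissue.

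Small structured RNAs and nuclear protein-coding genes made up most of the TPM. Protein-coding genes held 45.7 ± 0.912% and small structured RNAs 35.5 ± 0.838%, followed by mitochondrial genes with 11.1 ± 0.475%, long non-coding RNAs with 3.39 ± 0.327% and pseudogenes with 3.36 ± 0.0327%. A few entries, chosen after their values were seen, held much of the long non-coding and pseudogene shares. Gm26917, annotated as long non-coding, had a TPM of 12311 ± 1381. Rmrp, which the fixed lists place among structured small RNAs, was counted as long non-coding with 2923 ± 288. The pseudogenes Gm28661 and Gm10925 had 7425 ± 260 and 6251 ± 121. The most abundant entries of any nuclear class were Rn7s1 (chromosome 12, 69159295 to 69159594), Rn7s2 (chromosome 12, 69361182 to 69361481) and Rn7sk (chromosome 9, 78175303 to 78175633). Rn7s1 and Rn7s2 encode 7SL, the RNA of the signal recognition particle, and Rn7sk encodes 7SK, a regulator of transcription elongation. The 7SL genes had equal values because reads were divided between near-identical copies. Together they held 26.4 ± 0.696% of TPM but 3.47 ± 0.174% of expected counts, since TPM divides by an effective length. This is about the transcript length less a fragment length. The alignment-based values imply a fragment length of 100 nt in both libraries. The FASTQ-based values imply 378.5 nt in replicate 1 and 342.06 nt in replicate 2. The TPM shares of RNAs this short therefore depend on that setting. Of expected counts, protein-coding genes held 79.7 ± 0.173% and small structured RNAs 4.58 ± 0.188%. In the FASTQ-based quantification small structured RNAs held 0.0703 ± 0.0141% of TPM: the 67 entries shorter than 350 nt with at least 100 alignment-based counts in both libraries kept a median of 0 of those counts there, so the level of these short RNAs depends on the quantifier.

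Structured small RNAs of the fixed list had a median TPM of 5152, with 7 of 8 members detected, Rpph1, the RNA of ribonuclease P, at 7380 ± 151 and Rny3 at 0 counts in both animals. The 13 mitochondrial coding genes were all detected, with a median TPM of 2182. Cytochrome oxidase subunit mt-Co1 led with 6349 ± 303, ahead of mt-Cytb with 3457 ± 197 and mt-Nd1 with 3069 ± 9.60. Pseudogenes on chromosome 1 that are near-identical to mitochondrial genes, such as Gm28661 at 7425 ± 260, share reads with them, so the levels of those mitochondrial genes are uncertain.

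The most abundant nuclear protein-coding genes included genes of neuronal signalling and broadly expressed genes. Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase II (ENSMUSG00000024617.16, chromosome 18, 60925618 to 60988152), reached a TPM of 1120.1 ± 24.7. Snap25, a SNARE protein of synaptic vesicle fusion (chromosome 2, 136713453 to 136782428), reached 1113 ± 17.4, and Nrgn, a postsynaptic calmodulin-binding protein (chromosome 9, 37544492 to 37552904), 1028 ± 50.4. The calmodulin gene Calm2 stood at 971 ± 6.13 and the peptide-processing enzyme Cpe at 1041 ± 50.2. The broadly expressed genes Actb, Gapdh and Eef1a1 stood at 1071 ± 14.4, 1023 ± 75.9 and 999 ± 26.0. Gapdh had 14367 and 11027 alignment-based counts in replicates 1 and 2 but 26741 and 19818 FASTQ-based counts. Its level therefore depends on the quantifier. Snurf (chromosome 7, 59995449 to 60005049) reached 994 ± 35.01 but overlaps Snrpn and had 0 reads in the FASTQ-based quantification, so its own level is uncertain.

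Markers of neurons, astrocytes and myelinating oligodendrocytes were abundant, and markers of vascular and meningeal cells were lower. All 15 excitatory markers were detected, with a median TPM of 30.3, at percentile 70.4 of detected protein-coding genes. Slc17a7, the vesicular glutamate transporter of cortical projection neurons, stood at 617 ± 30.8 and the synaptic vesicle protein Sv2b at 157 ± 1.01. All 15 inhibitory markers were detected too, at percentile 75.6, led by somatostatin (Sst) with 189 ± 3.01 and the GABA-synthesizing enzyme Gad1 with 160 ± 16.8. Without length correction excitatory markers lay at percentile 86.8 and inhibitory markers at 60.6, so the order of these lists depends on the unit. The 13 astrocyte markers lay at percentile 84.9, with the glutamate transporter Slc1a2 at 939.8 ± 76.2 and Aldoc at 345 ± 18.97. The 13 markers of myelinating oligodendrocytes lay at percentile 90.5, with myelin basic protein (Mbp) at 744 ± 224.

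Oligodendrocyte precursor markers (10 of 10 detected) were at percentile 31.3, led by Olig1 with 53.0 ± 6.14 and Gpr17 with 21.7 ± 1.41. Microglial markers (14 of 14) were at percentile 51.7, among them Csf1r with 39.9 ± 2.27 and Ctss with 25.4 ± 1.17, and endothelial markers (11 of 11) at percentile 50.4, led by the glucose transporter Slc2a1 with 44.4 ± 5.62. For mural cells 9 of 10 markers were detected, at percentile 18.7, with Vtn at 30.8 ± 0.679 and Rgs5 at 25.8 ± 1.70. Meningeal fibroblast markers (8 of 9) lay at percentile 22.3, with Igf2 at 39.0 ± 8.73 and Col1a2 at 11.5 ± 0.318. Choroid plexus and ependymal markers (5 of 10) lay at percentile 0.503 (0 without replicate 1, 2.95 without replicate 2), and their highest member, transthyretin (Ttr), had TPM values of 96.0 and 4.79 in replicates 1 and 2. Erythroid markers (5 of 7) lay at percentile 68.9, with the haemoglobin genes Hbb-bs at 197 ± 36.9 and Hba-a1 at 190.0 ± 40.5. Counts without length correction placed precursors at percentile 51.1, microglia at 36.0, endothelium at 44.0 and erythroid cells at 30.6, and endothelium lay at 48.2 without replicate 2, so their side of the middle is open.

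**Figure D1:**
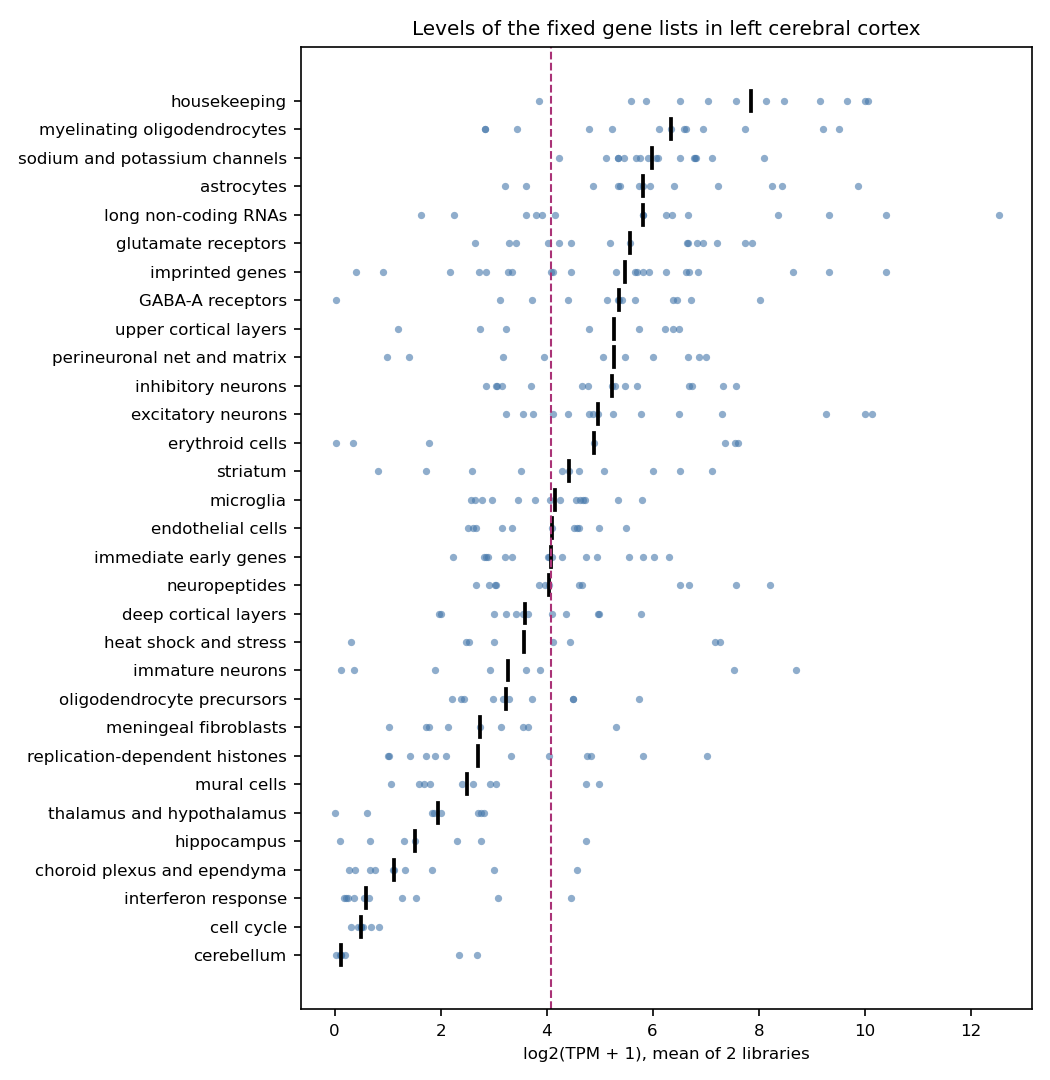
Each point is 1 gene of a fixed list, placed at its log2(TPM + 1) averaged over the 2 libraries; black ticks are list medians and the dashed line is the median of detected nuclear protein-coding genes (4.09). Structured small RNAs and mitochondrial genes are not drawn. Among the lists drawn, housekeeping and myelin genes have the highest medians, 7.85 and 6.35, and cerebellar and cell cycle genes the lowest, 0.12 and 0.50.

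Genes of upper cortical layers were more abundant than those of deep layers, and markers of other brain regions ranged from the level of cortical genes to almost no reads. The 8 upper-layer genes had a median TPM of 39.8 (percentile 76.2), with the transcription factor Cux2 at 89.8 ± 6.34 and Rasgrf2 at 82.2 ± 4.66. The 12 deep-layer genes had a median of 11.2 (percentile 38.8), with Tbr1 at 54.3 ± 8.62 and Etv1 at 31.0 ± 5.47. Striatal markers (10 of 11 detected) had a median of 20.9 (percentile 58.1), led by Ppp1r1b, the dopamine-regulated phosphoprotein DARPP-32 of striatal neurons, at 141 ± 35.7 and proenkephalin (Penk) at 92.4 ± 30.5. Without replicate 1 the striatal median lay at percentile 48.2. Hippocampal markers (5 of 7) had a median of 1.94 (percentile 5.17), led by Zbtb20 with 25.9 ± 0.325, and at percentile 9.42 without replicate 1 and 1.70 without replicate 2. The thalamic and hypothalamic list (3 of 8) lay at percentile 10.7 (0 without replicate 1, 24.04 without replicate 2) with an SD of 1.66 on the log2 scale, and its highest member Pmch had TPM values of 35.6 and 0.35 in replicates 1 and 2. Cerebellar markers (2 of 7) lay at percentile 0, led by Zic1 with 5.42 ± 0.431 and Car8 with 4.09 ± 0.0354.

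Receptor and channel genes stood well above the middle of the transcriptome. All 15 glutamate receptor genes were detected, at a median TPM of 46.7 (percentile 81.7), led by the AMPA receptor subunit Gria2 with 232 ± 11.0 and the NMDA receptor subunit Grin1 with 212 ± 19.3. Of the 13 GABA-A receptor genes 12 were detected (percentile 78.0), among them Gabrb2 with 82.6 ± 0.679. Gabra6, which is typical of cerebellar granule cells, had 1 and 0 counts, which allows up to 3 counts in replicate 2. All 16 sodium and potassium channel genes were detected at a median of 62.2 (percentile 86.8), among them the sodium channel subunits Scn2a with 138 ± 3.15 and Scn2b with 112 ± 4.95. Genes of the perineuronal net and matrix (9 of 10) lay at percentile 76.2, with the proteoglycan brevican (Bcan) at 127 ± 4.39, Lynx1 at 117 ± 1.05 and neurocan (Ncan) at 100.02 ± 6.14.

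Ratios of paired genes ranged widely. Slc17a7 exceeded the other vesicular glutamate transporter Slc17a6 49.8-fold (log2 ratio 5.64 ± 0.43) and the vesicular GABA transporter Slc32a1 14.2-fold (3.82 ± 0.31). The chloride exporter Slc12a5 exceeded the chloride importer Slc12a2 13.6-fold (3.76 ± 0.29). Among receptors, Gria2 exceeded Gria1 2.32-fold (1.21 ± 0.06). Grin2a was below Grin2b by a log2 ratio of -0.28 ± 0.15, a difference of under 2-fold in both animals. Sst exceeded parvalbumin (Pvalb) 4.98-fold. Other ratios were 6.17-fold for the sodium channels Scn8a over Scn3a (2.63 ± 0.15), 6.52-fold for the scaffold genes Dlg4 over Dlg3 (2.71 ± 0.07), 6.28-fold for the astrocytic glutamate transporters Slc1a2 over Slc1a3 (2.65 ± 0.07), 3.76-fold for Camk2a over Camk2b (1.91 ± 0.04) and 3.11-fold for Gad1 over Gad2 (1.64 ± 0.19). Kcnc1 over Kcnd2 was 1.73-fold (0.79 ± 0.08). In 12 of 14 pairs the difference was at least 2-fold in both libraries, and in all pairs it had the same direction in both. An exact sign-flip test of 2 animals cannot go below p = 0.5. Without length correction 10 of the 14 pairs differed at least 2-fold in both libraries. Gad1 over Gad2 was then 1.34-fold, Dlg4 over Dlg3 3.98-fold, Slc12a5 over Slc12a2 8.996-fold, Slc1a2 over Slc1a3 14.4-fold and Grin2a over Grin2b -0.98 on the log2 scale.

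**Figure D2:**
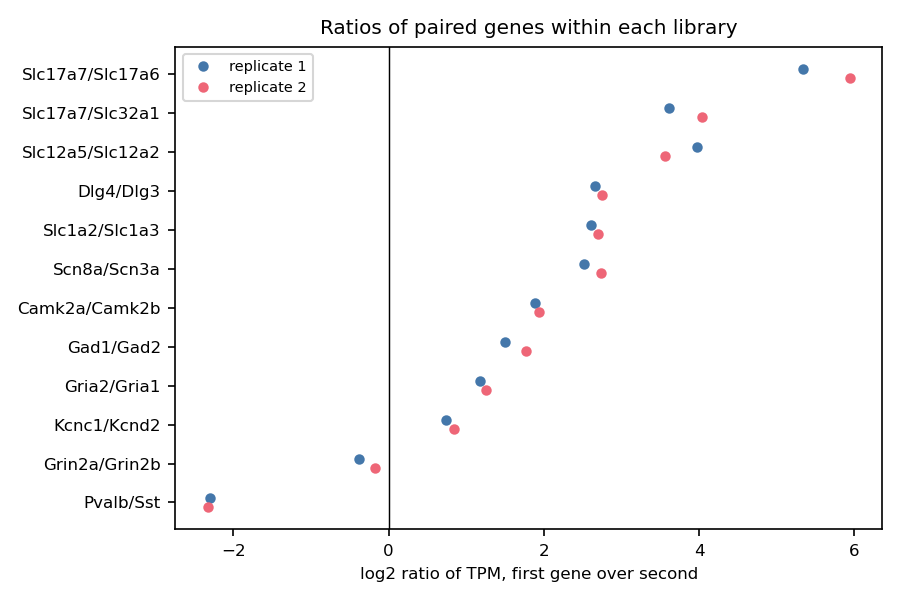
The log2 ratio of TPM of the first over the second gene of each of 12 pairs is shown for each library, replicate 1 in blue and replicate 2 in red. Slc17a7 over Slc17a6 has the largest ratio, 5.64 on average, and Pvalb over Sst the lowest, -2.32.

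Peptide, activity and stress genes covered a wide range. All 13 neuropeptide genes were detected at a median TPM of 16.0 (percentile 49.1, or 57.4 without replicate 2), led by cholecystokinin (Cck) with 295 ± 4.41, Sst and neuropeptide Y (Npy) with 102 ± 0.191. All 16 immediate early genes, which neurons transcribe within minutes of activity, were detected at percentile 49.8, led by Egr1 with 80.5 ± 26.6 and Egr3 with 63.8 ± 1.54. Without replicate 2 their median lay at percentile 61.2. Heat shock and stress genes (7 of 8) lay at percentile 38.1, with the chaperones Hsph1 at 154 ± 23.4 and Hspa5 at 146 ± 37.3. With undetected members left out, this list lay at percentile 50.9. Interferon response genes (4 of 10) had a median of 0.525, with Ifi27 at 20.99 ± 0.495 and Ifit3 at 1.89 ± 0.106.

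Proliferation genes were at the edge of detection, while imprinted and long non-coding RNAs were abundant. No cell cycle gene of 8 reached a TPM of 1 in both animals, and the highest was Ccnb1 with 0.780 ± 0.0141. Immature neuron genes (6 of 8) lay at percentile 31.9, with Stmn1 at 418 ± 11.8 and Tubb3 at 185 ± 16.7. Without length correction they lay at 60.4. Replication-dependent histone genes (10 of 12) lay at percentile 21.9, with Hist1h4h at 129 ± 2.68 and Hist1h4d at 55.2 ± 3.33, although near-identical copies share reads. Imprinted genes (20 of 22) lay at percentile 80.2, led by Meg3 with 1366 ± 229, Rian with 639 ± 57.4 and Snrpn with 400.4 ± 13.8. All 15 long non-coding RNAs of the list were detected at percentile 84.9, with Malat1 at 5948 ± 909 and Snhg11 at 331 ± 68.2. The 12 housekeeping genes lay at percentile 98.1, with Ppia at 811 ± 39.5 and Ywhaz at 569 ± 18.8 below Actb and Gapdh.

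A single transcript dominated some genes, while the output of others was spread over several. In 10 of 20 genes 1 transcript held at least 50% of TPM in both libraries. The leading Snap25 transcript (2116 nt) held 85.2 ± 0.580%, Mapt-204 of the microtubule protein tau 69.1 ± 3.29%, and Mbp-211 69.8 ± 1.56%. Gria2-202 held 52.4 ± 3.52% on average but 49.9% in replicate 2, so Gria2 is not among the 10. The leading transcript was the same in both libraries for 19 of 20 genes, Bdnf being the exception, and in both quantifications for 16. Among the 4 that differed, Pkm, which encodes a pyruvate kinase, was led by Pkm-202 with 48.8 ± 0.460% in the alignment-based table and by Pkm-201 with 51.1 ± 0.875% in the FASTQ-based one. The leaders were for Meg3 Meg3-203 with 26.2 ± 1.90% and Meg3-209 with 25.6 ± 1.44%, and for Bdnf Bdnf-209 with 27.6 ± 6.60% and Bdnf-201 with 33.7 ± 1.28%. Mbp-211 kept its rank in the FASTQ-based table but held 29.3 ± 4.54% there.

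Replicate 1 held more immediate early, striatal and stress RNA, and replicate 2 held more myelin RNA. In CPM all 16 immediate early genes were higher in replicate 1, with a median log2 ratio (replicate 2 over replicate 1) of -0.77 at percentile 0 of random lists. Arc, Npas4 and Fos, genes of the response to neuronal activity, were 2.56-fold (95% interval 2.43 to 2.70), 2.98-fold (2.57 to 3.47) and 2.75-fold (2.40 to 3.15) higher in replicate 1, chosen after their values were seen. All 11 striatal markers were also higher in CPM in replicate 1 (median -0.67), as were all 8 stress genes (-0.49) and all 7 erythroid markers (-0.44). Some members differed by no more than counting error: the stress gene Atf3 had 9 and 7 counts, a ratio of 1.15 (95% interval 0.380 to 3.62). In the FASTQ-based quantification the erythroid median was -0.13, at the edge of the random range (-0.13). All 13 myelin genes were higher in replicate 2, with a median of 0.57 at percentile 100, and 6 of them were at least 1.5-fold higher.

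Of 32 lists compared, 17 lay outside the random range, 12 higher in replicate 1 and 5 in replicate 2, where 1.6 would be outside by chance if genes of a list varied independently. Besides those above, lists higher in replicate 1 were the thalamic and hypothalamic genes (-0.33, or -1.02 with a pseudocount of 0.1, 6 of 7 members with counts), choroid plexus and ependyma (-0.29, or -0.53), neuropeptides (-0.15), inhibitory neurons (-0.14), structured small RNAs (-0.14), imprinted genes (-0.11), housekeeping genes (-0.11) and GABA-A receptors (-0.10). Higher in replicate 2 were long non-coding RNAs (0.26, 12 of 15), hippocampal markers (0.23), endothelial cells (0.12) and excitatory neurons (0.05). Lists inside the random range included astrocytes (-0.10), microglia (-0.08), oligodendrocyte precursors (0.03), mural cells (0.10), meningeal fibroblasts (-0.14), upper (-0.06) and deep (0.05) cortical layers, cerebellum (0.02), interferon response (0.03), cell cycle (0.01), immature neurons (0.05), glutamate receptors (0.01), sodium and potassium channels (-0.03), perineuronal net and matrix (-0.06) and histones (0.002). These are descriptions of 2 libraries. Structured small RNAs had a median of 0.10 in the FASTQ-based quantification, which holds almost no reads of their most abundant members. Rn7s1 had 0 and 1 counts there and Rn7sk 0 and 2, so that value says nothing about their direction. Spike-in scaling, which moves all genes nearly alike, gave excitatory neurons -0.02, still above the random range of that setting. The inhibitory, hippocampal, GABA-A, imprinted, structured small RNA and housekeeping lists each lay inside the random range under at least 1 alternative. Of the lists inside it, meningeal fibroblasts lay outside with spike-in scaling (-0.21), in the FASTQ-based quantification (-0.17) and after correction for GC content and length (-0.14). Glutamate receptors did so with TPM as deposited (0.17), in the FASTQ-based quantification (0.003) and after that correction (0.04), histones in the FASTQ-based quantification (0.28), and deep layers over members with a mean CPM of at least 5 (0.14). Entries of 350 to 500 nt kept a median of 0.287 of their alignment-based counts in the FASTQ-based table in replicate 1 and 0.447 in replicate 2. That table can therefore place lists of short RNAs higher in replicate 2. Whether this accounts for the histone or erythroid values there was not tested.

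**Figure D3:**
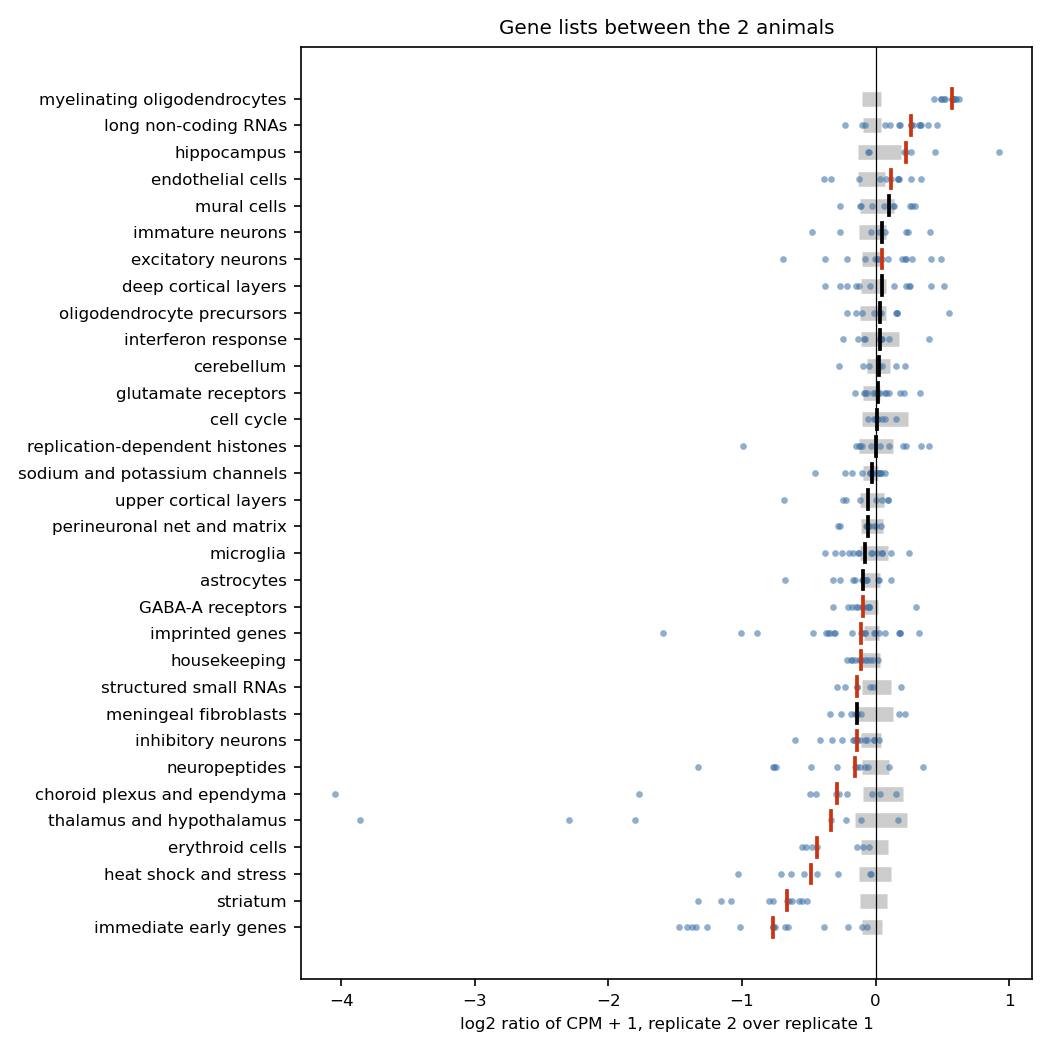
Points are genes of each list at their log2 ratio of CPM + 1, replicate 2 over replicate 1; ticks are list medians, red where the median lies outside the central 95% of random lists (grey bars). Immediate early genes have the lowest median, -0.77, and myelin genes the highest, 0.57. The structured small RNA median is 0.10 in the FASTQ-based quantification, which holds almost no reads of the most abundant of these RNAs. With spike-in scaling, which moves all genes nearly alike, the excitatory median is -0.02 and still above the random range.

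A small set of genes differed at least 2-fold between the animals, most of them higher in replicate 1, with a more even split at 1.5-fold. Transthyretin (Ttr, ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), a thyroid hormone carrier made by the choroid plexus, had 2172 and 91 counts in replicates 1 and 2, which is 21.3-fold higher (95% interval 17.2 to 26.5). Pmch, which encodes the hypothalamic melanin-concentrating hormone (ENSMUSG00000035383.7, chromosome 10, 88091072 to 88092375), had 482 and 4 counts, or 107-fold (41.7 to 396). Dlk1, an imprinted Notch-family ligand (chromosome 12, 109452823 to 109463336), was 3.72-fold higher (2.90 to 4.83) and Baiap3 (chromosome 17, 25242659 to 25256364) 3.04-fold higher (2.60 to 3.56) in replicate 1. In replicate 2 the extracellular matrix gene Thbs4 (chromosome 13, 92751590 to 92794818) was 3.52-fold higher (2.77 to 4.51), Mid1 (chromosome X, 169685199 to 170005736) 2.18-fold (1.87 to 2.55) and Gm2115 (chromosome 7, 84528954 to 84583531) 2.15-fold (1.86 to 2.49).

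In all, 25 of 11721 genes with a mean CPM of at least 5 differed at least 2-fold, 21 higher in replicate 1 and 4 in replicate 2. At 1.5-fold the split was 79 to 52, and 98.9% of genes lay within that range. Of the 25 genes 22 were protein-coding, and 19 also differed 2-fold in the same direction in the FASTQ-based quantification. Gm14440 (399 and 0 counts) and Gm14288 (0.04 and 279 counts) both lie on chromosome 2. Their FASTQ-based counts, 0 and 36.8 for Gm14440 and 465 and 313 for Gm14288, did not show these differences, so both are uncertain. The small nuclear RNA gene Gm24497 (chromosome 1, 72244213 to 72244403), chosen after its values were seen, had 3132 and 15.3 counts. It had 0 in the FASTQ-based table, where entries shorter than 350 nt kept a median of 0 counts. That table therefore cannot check the difference, which is also uncertain. With 1 library per animal, none of these differences has a replicate check.

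**Figure D4:**
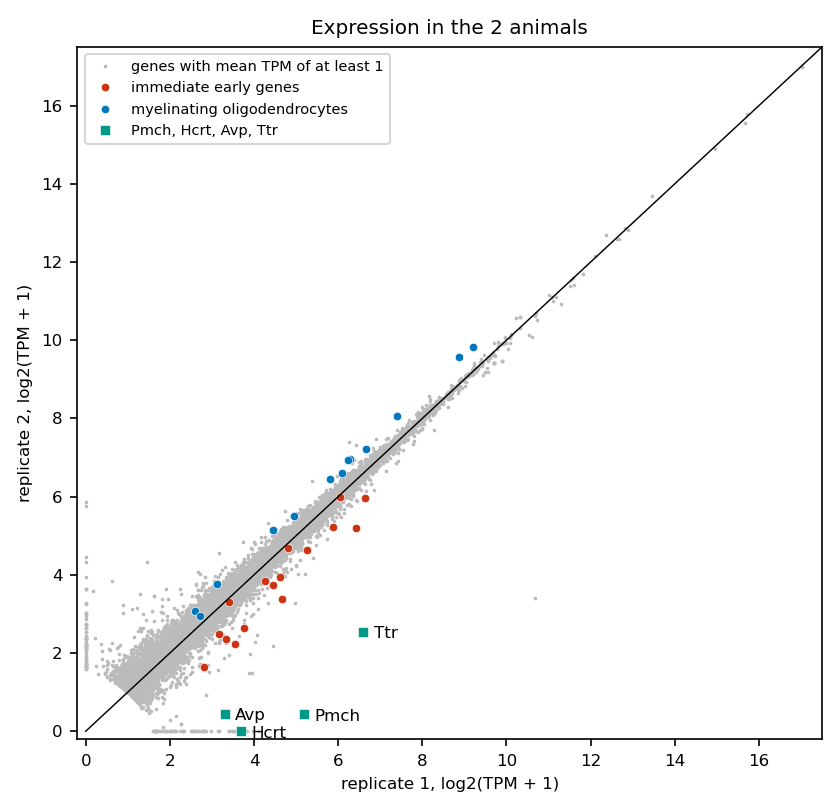
Each grey point is a gene with a mean TPM of at least 1, placed at log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), and the line marks equal values. Most immediate early genes (red) lie below the line, myelin genes (blue) above it, and Ttr, with TPM values of 96.0 and 4.79, lies far below it with Pmch, Hcrt and Avp.

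Spike-in RNAs took similar shares of both libraries. They held 0.350% of expected counts in replicate 1 (Wilson 95% interval 0.348 to 0.352%) and 0.378% in replicate 2 (0.375 to 0.380%), a difference larger than counting error. Of 96 spike-ins 60 had a count in both libraries and 24 in neither. Their log2(TPM + 1) correlated with a Pearson r of 0.998 and a Spearman rho of 0.958 over 72 spike-ins, and the log2 ratio between libraries had an SD of 0.15 over 27 spike-ins with at least 50 counts. The phiX174 control had 0 counts in both.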

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

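Entries of the gene tables that carry only a number and no gene name were used in no comparison. Their expected counts summed to 2 in replicate 1 and 4.93 in replicate 2 over 26248 entries, of which 2 and 5 had a count. The sum in replicate 2 was flagged because it exceeds 3 counts. That limit applies to a single entry with a count of 0 and not to a sum over many entries, so passing it says nothing.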

How the results depend on the processing

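The correction for GC content and length, the additional hypothalamic list and the floor for members without reads were chosen after seeing the data; the other alternatives were planned. A limit for a move was set for each kind of result. For class shares it was the spread between the libraries. For list percentiles, the coefficient of variation and counts of genes or lists it was a fixed amount or ratio. Of 621 alternative values for 94 results, 462 stayed within their limit and 157 moved past it. The other 2, both in lists outside the random range, changed sign. Another 12 list medians, all in lists inside the random range, also changed sign and are counted by the size of their move. Of these 14 sign changes, 8 came with another factor per library (spike-ins or DESeq2), which moves a list and its random lists nearly alike, so they say nothing about the list; 1 of the 8 is the excitatory list. The numbers of detected nuclear protein-coding genes, lists above the middle, subunit pairs and isoform genes stayed within 1.5 times under every alternative run. So did the number of lists outside the random range (14 to 18 against 17). For other classes only the FASTQ-based quantification was compared. It detected 1721 long non-coding, 706 pseudogene, 4 small structured RNA and 13 mitochondrial genes, against 805, 671, 213 and 15. The detected numbers of long non-coding and small structured RNAs therefore depend on the quantifier. The Pearson r between replicates was 0.970 with a pseudocount of 0.1, 0.991 over genes with a TPM of at least 1 in both libraries, 0.991 with FPKM and 0.987 in the FASTQ-based quantification, where the coefficient of variation was 0.114. Class shares for protein-coding, small structured, mitochondrial, long non-coding and pseudogene RNA were 79.7, 4.58, 8.34, 5.36 and 1.28% of expected counts and 73.5, 0.0703, 16.5, 4.72 and 3.61% in the FASTQ-based quantification. Without mitochondrial and spike-in entries, which leaves no mitochondrial share, they were 51.8, 40.3, 3.84 and 3.81%. Spike-ins held 0.717% of TPM. Against 25 genes differing between animals there were 59 at a mean CPM of at least 1, 74 with no minimum, 131 at 1.5-fold and 42 in the FASTQ-based quantification; the first 3 settings admit more genes by construction.

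Median log2 ratios of lists, replicate 2 over replicate 1, moved as follows, and the cause was not tested. Spike-in scaling gave excitatory neurons -0.025, still above the random range at percentile 98.6, inhibitory neurons -0.21, myelin 0.51, endothelium 0.047, erythroid cells -0.51, striatum -0.73, immediate early genes -0.84, stress -0.55, GABA-A receptors -0.17, neuropeptides -0.22, imprinted genes -0.18, long non-coding RNAs 0.19, structured small RNAs -0.21 and housekeeping genes -0.18, and it placed the median of 13375 protein-coding genes at -0.10 against -0.03 with TMM. TPM as deposited gave excitatory neurons 0.14, inhibitory neurons -0.064, myelin 0.64, endothelium 0.25, erythroid cells -0.36, striatum -0.54, hippocampus 0.35, thalamus and hypothalamus -0.55, immediate early genes -0.68, GABA-A receptors -0.037, neuropeptides -0.30, imprinted genes -0.011, structured small RNAs -0.054 and housekeeping genes -0.033. A pseudocount of 0.1 gave choroid plexus -0.53, hippocampus 0.34, thalamus and hypothalamus -1.02, stress -0.56 and the additional hypothalamic list -1.06 against -0.25. Members with a mean CPM of at least 5 gave erythroid cells -0.50, thalamus and hypothalamus -0.22 and long non-coding RNAs 0.22. The FASTQ-based quantification gave myelin 0.52, erythroid cells -0.13, GABA-A receptors -0.15, imprinted genes -0.15 and long non-coding RNAs 0.22. It gave structured small RNAs 0.10, but with almost no reads of their most abundant members, such as 0 and 2 counts for Rn7sk. That change of sign says nothing about their direction. After the GC and length correction inhibitory neurons were at -0.073, endothelium at 0.18, erythroid cells at -0.36, structured small RNAs at -0.048 and housekeeping genes at -0.063. Setting members without reads to 3 counts moved no list's median, so it says nothing about stability. The choroid plexus list gave no value for members with a mean CPM of at least 5, since too few members remained. Genes at a few counts, such as most hypothalamic and choroid plexus markers, are limited by depth.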

Other observations

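Several genes of hypothalamic neurons, but not all examined, were higher in replicate 1. Hcrt, which encodes the wakefulness peptide orexin, had 120 counts in replicate 1 and 0 in replicate 2, at least 28.5-fold higher by the exact 95% interval. Avp, which encodes vasopressin, had 88.3 and 3 counts, a ratio of 26.1 (95% interval 8.65 to 129). Among genes of the additional hypothalamic list, the transcription factors Sim1, Otp and Nkx2-1 had 31 and 1, 18 and 0, and 25 and 6 counts in replicates 1 and 2, while Pomc had 20 and 19 and Hdc 12 and 11. Of the peptides also made in striatum and cortex, Tac1 had 612 and 200 counts and Penk 2949 and 1529. Clic6, a choroid plexus gene, had 113 and 10 counts. These genes were chosen after their values were seen, apart from those the naming rule covers.

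For the patterns weighed here, the tests of stress genes, of choroid plexus genes, of the FASTQ-based quantification and of other non-neuronal lists were chosen after the results were seen, and those of GC content and length and of the additional hypothalamic list were written before their results but added after seeing the data. The series has 1 group, so the design names no biological explanation and none of that kind was tested. The explanations tested concern handling, dissection, tissue composition and processing.

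Pmch, Hcrt, Avp and Ttr were higher in replicate 1. Assignment of reads by 1 quantifier is argued against, since the smallest difference among these genes was 14.2-fold in the FASTQ-based quantification with counts below 3 raised to 3. Tissue from the hypothalamus in replicate 1 may account for the peptide genes: the additional list of 12 hypothalamic genes, 9 of them with counts, had a median log2 ratio of -0.25 at percentile 0.01 of random lists, with 7 of 9 higher in replicate 1. Choroid plexus tissue may account for Ttr. The 9 other members of the choroid plexus and ependyma list had a median of -0.27 at percentile 0.025. Of the 9, 7 were higher in replicate 1, most of them at low counts. The shift of the whole list was known when this test was chosen, so the test is no independent support. Dissection that took in neighbouring tissue and a difference between the animals both stay open.

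Immediate early genes were higher in replicate 1. A trend with GC content or length is argued against as the whole cause, since after its removal the median log2 ratio was -0.76, still outside the random range. A stress response to handling may contribute: the heat shock and stress list had a median of -0.49, below the random range. That value was known when the test was chosen, so it is no independent support. The striatal list was also higher in replicate 1, and the animals' activity before tissue was taken is not given in the sources used here, so these stay open.

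Myelin genes were higher in replicate 2. A trend with GC content or length is argued against by a median of 0.60 after its removal. A lower neuronal share would raise the other non-neuronal lists alike, but the highest median among astrocytes, microglia, endothelium and oligodendrocyte precursors was 0.12, far below the 0.57 of myelin genes. More white matter in the tissue and a difference in myelination between the animals may each be candidate explanations and were not tested.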
